A study of Homo sapiens with 4 samples.

How the data were processed

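The data are the expression values of 4 Affymetrix arrays, 2 of vehicle-treated and 2 of forskolin-treated human adipocytes. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was made from 10 µg of it by the manufacturer's standard procedure. Per the submitters' processing notes, Affymetrix Expression Console was used, with no version given. The algorithm, the background correction and the normalisation between arrays are not given in the sources used here. The values as deposited by the authors are on a log scale between 2.96 and 15.2, taken as log2 because of that range, since the base is not stated. The quartiles of the 4 arrays are close, with the lower between 4.81 and 4.86 and the upper between 8.12 and 8.23, but whether the arrays were normalised together is not stated. If they were set to a common distribution, a shift of all transcripts in one direction cannot be seen. Probe levels are not comparable between probe sets, and values of dim probe sets can be compressed towards the background, so that their fold changes may be understated. This was not tested. The filter floor is a rank within the array, not a detection call.

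Of the 54675 probe sets, 41097 were listed with 1 gene symbol in the platform annotation, 1801 with several, and 11777 were unnamed here. Probe sets with several symbols or none were not used. Gene numbers matched the NCBI RefSeq gene table of GRCh38.p14 for 41043 probe sets, and 0 symbols needed an update. Sex-linked probe sets (61) were left out before any fit. A probe set was kept if it lay above the 30th percentile of its array on at least 2 of the 4 arrays, a floor of 5.10 to 5.16 log2, which left 30995. For each gene the probe set with the highest mean was tested, giving 16004 genes, of which 8053 had more than 1 probe set passing the filter. For 1056 genes the chosen probe set was of the kind that can cross-hybridise (suffix _x_at).

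Groups were taken from the sample titles. Forskolin was compared with vehicle on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 4.42 degrees of freedom in all), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The replicate number was not a term of the model, because the labels do not say that a number stands for an individual. The labels call the arrays biological replicates, and p-values measure the spread between these cultures. Intervals are at the 95% level. Before the data were examined, 34 gene lists were fixed, 26 by function and 8 by cell type, as were the tests, the alternatives and the rule for named genes. The lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists, and also with camera at an estimated correlation and with fry. The lists hold 701 genes, of which 598 were tested, and some genes stand in more than 1 list (742 entries, 633 tested). With an estimated correlation 0 lists passed. That form of camera uses only the residual degrees of freedom, which are few here, so hardly any list can pass. Its adjusted p therefore does not tell whether correlation between genes undid a result. Fry, which asks whether a list's genes move one way on balance, passed 1, the cyclic AMP and CREB targets (adjusted p = 0.0125). In its mixed form, which asks whether a list's genes change in either direction, fry passed 16.

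The named genes are the 12 with the largest fold in each direction among the genes past the threshold whose groups did not overlap, up to 4 members past the threshold of each list described (or the 2 with the smallest p where none passed), and a fixed set of cyclic AMP, thermogenic, adipocyte and secreted-factor genes. CREM, PRKAR2B, KRT18 and SLC7A10 were chosen after their values were seen. PCSK1, PENK and IL33 were put in the fixed set with knowledge of earlier work on such cells. No probe set was listed with PCSK1 as its only gene symbol, so PCSK1 was not tested.

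Scripts were tested on simulated data with the real gene means and the moderated SD of the fit, drawn as independent noise without a replicate effect. In 10 simulations of forskolin against vehicle with 200 changed genes among 16004, 66% of the genes changed 2-fold were recovered, 97.2% of those changed 4-fold and 98.8% of those changed 8-fold, and 7.92% of the calls were false. In 10 simulations with no changed gene there were 4 calls in all. The recovery rates may not hold for the data, where 381 genes were at least 2-fold higher and 346 lower but 71 passed. PDK4, 30.9-fold higher, was among those that did not pass by limma (adjusted p = 0.136). Camera called a list shifted by 1 log2 unit in 10 of 10 simulations and 3 of 320 unshifted lists, in simulations without correlation between genes. Array control probe sets served as a check of RNA integrity. The difference between the 3' and 5' probe sets was 0.01 to 0.03 log2 for GAPDH and 1.00 to 1.21 for ACTB, highest for ACTB on forskolin replicate 1.

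The alternatives were quantile normalisation of the deposited values, median centring, no filter, a filter at the 50th percentile, the mean of all probe sets of a gene, every probe set on its own, eBayes without trend or with robust estimation, the replicate number as a block, each array left out in turn, an adjusted p under 0.1 and a minimum fold of 2. The test without cross-hybridising probe sets was chosen after the data were seen. No genome coordinates were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.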

Results

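Transcript levels were measured on 4 Affymetrix oligonucleotide arrays of human adipocytes grown from cells of adipose tissue capillaries. Adipose explants of 2 individuals had been kept in a hydrogel under conditions that promote vessel growth, and the capillary sprouts were passaged onto plastic and differentiated into adipocytes. After 12 days of differentiation the cells received vehicle or 50 µM forskolin for 7 days. Forskolin is a plant diterpene that activates adenylate cyclase and so raises cyclic AMP, the second messenger of beta-adrenergic stimulation in fat. Each condition had 2 arrays, described as biological replicates, and the comparison asked which transcripts differ after sustained adenylate cyclase activation. The array medians were 6.26 and 6.29 on the log2 scale for the vehicle arrays and 6.29 for both forskolin arrays. The number of arrays limits the precision of every value below. Errors are the standard error (SE) of the limma fit unless SD is stated, and n = 2 per group throughout.

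Forskolin changed 71 of the 16004 genes tested at a Benjamini-Hochberg adjusted p under 0.05 by limma, 36 higher and 35 lower. Each of the 71 differed at least 2.08-fold, and in each the 2 forskolin values lay on one side of both vehicle values. Among these, the largest increases measured were those of the cyclic AMP phosphodiesterases PDE4D (22.5-fold) and PDE4B (21.2-fold), and the largest decreases those of KRT19 (15.9-fold lower), a keratin of simple epithelia, and KRTAP1-5 (14.3-fold lower), a keratin-associated protein. Both vehicle values of PDE4B, HPD, LINC00473, TAC1, ST8SIA4, PF4V1 and VASH2 and both forskolin values of KRT19 and PRSS12 lay below the filter floor of their arrays, as did 1 forskolin value of MYOZ2, TRIM59 and RGS7. Folds against such dim values may be understated, and the order of these genes by fold is not exact. On the first principal component, which held 66.5% of the variance, both forskolin arrays (43.5 and 12.6) lay on the opposite side of 0 from both vehicle arrays (-19.7 and -36.4). The second component held 26% and parted the arrays by replicate number. Both replicate 1 arrays lay above 0 on it and both replicate 2 arrays below. At an unadjusted p under 0.05 there were 2249 genes, 1039 higher and 1210 lower. The groups did not overlap in 47.1% of the genes tested, where chance gives 33.3% for 2 arrays against 2. Every adjusted p among the 71 lay between 0.0163 and 0.0498, and the number of calls depended on single arrays. Without vehicle replicate 1 or without vehicle replicate 2 limma called 0 genes, with 1329 and 1168 genes at an unadjusted p under 0.05, whereas 19 were called without forskolin replicate 1 and 229 without forskolin replicate 2. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.333. Over genes, the difference of vehicle replicates 1 and 2 correlated at 0.598 with that of forskolin replicates 1 and 2. The fit reported here counts this shared difference as error. With the replicate number as a block limma called 1333 genes, with 18 adipocyte markers and 22 respiratory chain genes among those higher. The labels do not say that a replicate number stands for an individual.

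Targets of cyclic AMP and its transcription factor CREB were higher after forskolin. Of the 26 measured, 5 rose over all genes tested, 15 rose and 1 fell when adjusted over the list alone, and the median log2 fold change was 1.44. PDE4D, which degrades cyclic AMP, rose from 5.80 ± 0.025 (SD, n = 2) to 10.30 ± 0.073 on the log2 scale, a log2 fold change of 4.50 ± 0.12 (adjusted p = 0.0163). PDE4B rose by 4.41 ± 0.24 (adjusted p = 0.0341), PDE7B, another cyclic AMP phosphodiesterase, by 2.11 ± 0.14 (adjusted p = 0.0426), and the orphan nuclear receptor NR4A2 by 2.76 ± 0.14 (adjusted p = 0.0341). CREM, a transcription factor of the CREB family named after its values were seen, rose by 1.83 ± 0.13 (adjusted p = 0.0426), with its 5 probe sets between 0.02 and 2.07. NR4A1 did not pass, at 0.47 ± 0.17 (adjusted p = 0.336). The list passed camera (adjusted p = 1.17e-12), and its adjusted p was 0.474 with an estimated correlation. The estimate was -0.0293, below the preset 0.01, so correlation between genes does not account for the higher value. Components of the cyclic AMP pathway itself, the receptors, cyclases and kinase subunits and inhibitors, did not pass, with a median of 0.022 over 25 genes (adjusted p = 0.81). Of the 25, 3 were higher and 3 lower at an unadjusted p under 0.05 and 0 passed when adjusted over the list alone, with the kinase inhibitor gene PKIB at -2.80 ± 0.68 (adjusted p = 0.242) and the regulatory subunit gene PRKAR2B at 2.16 ± 0.79 (adjusted p = 0.352). The probe sets of PDE4D ranged from 0.54 to 4.50, with 2.70 for their mean (adjusted p = 0.0263), the 2 of PDE4B were at 1.97 and 4.41, with 3.19 for their mean (adjusted p = 0.0478), and the NR4A2 probe set is of a kind that can cross-hybridise.

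**Figure D1:**
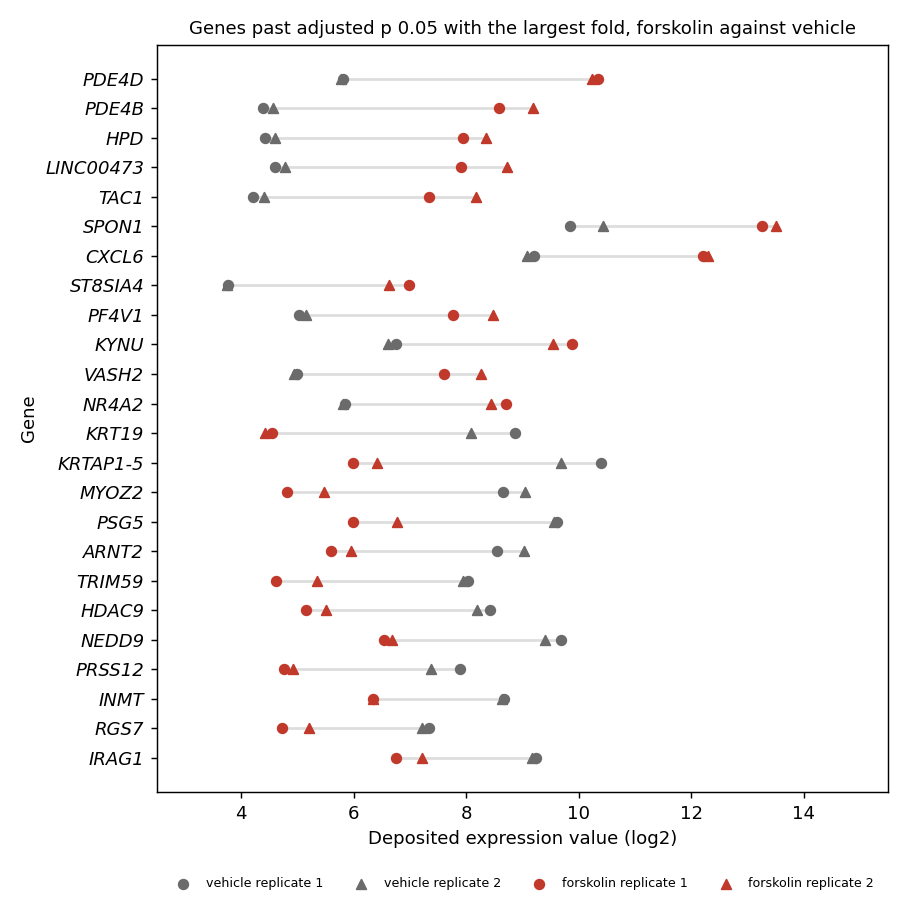
Deposited log2 expression value (x axis) of the 12 genes with the largest increase and the 12 with the largest decrease past an adjusted p of 0.05 (y axis); each point is 1 array, grey for vehicle and red for forskolin, and the marker shape gives the replicate number. For each of the 24 genes both red points lie on one side of both grey points, from 5.80 to 10.30 on average for PDE4D and from 8.48 to 4.48 for KRT19.

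Among the other genes with the largest increases were HPD, an enzyme of tyrosine breakdown, at 3.65 ± 0.18 log2 (adjusted p = 0.0341), and KYNU, kynureninase of the tryptophan pathway, at 3.03 ± 0.17 (adjusted p = 0.0341). The long noncoding RNA LINC00473 rose by 3.63 ± 0.31 (adjusted p = 0.0469), and the matrix protein gene SPON1 rose 9.50-fold to a mean of 13.38 log2, although with the mean of its probe sets it did not pass (2.97, adjusted p = 0.0517). The sialyltransferase gene ST8SIA4 rose 8.26-fold and VASH2, a vasohibin, 7.84-fold, although the 3 VASH2 probe sets ranged from 0.16 to 4.12 log2. TAC1, which encodes substance P and neurokinin A, rose by 3.46 ± 0.31 log2 (adjusted p = 0.0498). It was the 1 of 14 measured neuroendocrine and prohormone processing genes that rose over all genes tested, while 4 rose and 3 fell when adjusted over the list alone, and the list did not pass (median 0.11, adjusted p = 0.46). PENK, the enkephalin precursor, had a log2 fold change of 2.91 ± 0.29 (adjusted p = 0.0563), with a second probe set at 0.20 and their mean at 1.55 (adjusted p = 0.0531), and IL33, an alarmin cytokine, one of 2.73 ± 0.30 (adjusted p = 0.0667). Neither passed over all genes, and both were chosen with knowledge of earlier work on such cells, so their direction is not independent evidence.

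Several chemokine genes rose. CXCL6 rose by 3.12 ± 0.11 log2 (adjusted p = 0.0333), CXCL1 by 2.33 ± 0.13 (adjusted p = 0.0348) and CXCL2 by 2.30 ± 0.16 (adjusted p = 0.0426), while TNFAIP3, an inhibitor of NF-kappaB signalling, fell by 1.45 ± 0.12 (adjusted p = 0.0469). Of the 27 measured inflammatory cytokine and chemokine genes these 3 rose and 1 fell over all genes tested, 9 rose and 6 fell when adjusted over the list alone, and the list did not pass as a whole (median 0.20, adjusted p = 0.151) except without forskolin replicate 1 (median 0.28, adjusted p = 0.0312). PF4V1 rose 8.20-fold, but it is nearly identical in sequence to PF4, so its identity is uncertain, as is that of CXCL2 within its family. Among TGF-beta and BMP signalling genes, INHBA, the activin A subunit, rose by 2.52 ± 0.16 and BMP6 by 2.02 ± 0.13 (both adjusted p = 0.0426), and GREM1, a secreted BMP antagonist, fell by 1.96 ± 0.10 (adjusted p = 0.0341). The other 20 of the 23 measured did not pass over all genes, 3 rose and 4 fell when adjusted over the list alone, and the median was -0.010 while the mean was 0.012 (adjusted p = 0.981). With the mean of all its probe sets BMP6 was at 0.86 (adjusted p = 0.0814).

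The genes that fell furthest included KRT19 (-4.00 ± 0.29 log2, adjusted p = 0.0426), KRTAP1-5 (-3.84 ± 0.31, adjusted p = 0.0461) and MYOZ2, a sarcomere protein of the Z-disc (-3.71 ± 0.28, adjusted p = 0.0426). ARNT2, a bHLH-PAS transcription factor, fell 8.08-fold, the histone deacetylase gene HDAC9 7.88-fold, and the focal adhesion scaffold gene NEDD9 7.70-fold. TRIM59 fell 8.02-fold, PRSS12 6.89-fold, INMT 4.98-fold, RGS7 4.97-fold and IRAG1 4.68-fold, with adjusted p between 0.0341 and 0.0498. PSG5 fell 9.32-fold, but its probe set can cross-hybridise within the pregnancy-specific glycoprotein family and a second one gave -0.31 log2. With the mean of all probe sets of a gene, HDAC9 was at -1.21 (adjusted p = 0.0587), RGS7 at -1.39 (adjusted p = 0.0683), PSG5 at -1.76 (adjusted p = 0.0613), IRAG1 at -1.53 (adjusted p = 0.0537), PRSS12 at -2.11 (adjusted p = 0.0531) and MYOZ2 at -3.43 (adjusted p = 0.0531), none of them past the threshold. NEDD9 was at -1.56 and passed (adjusted p = 0.0458).

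Contractile genes and targets of YAP or SRF, transcription regulators that respond to the actin cytoskeleton, were lower after forskolin. The median log2 fold change over 21 genes was -0.76, and 20 of the 21 were lower. By limma 0 of the 21 passed over all genes tested and 13 had an unadjusted p under 0.05, and 6 fell when adjusted over the list alone. LMOD1, a smooth muscle actin nucleator, was at -1.73 ± 0.16 (adjusted p = 0.0522), or -1.05 with the mean of its 2 probe sets (adjusted p = 0.064), and AJUBA at -1.60 ± 0.33 (adjusted p = 0.195). The list passed camera (adjusted p = 6.28e-10), and its adjusted p was 0.879 with an estimated correlation. The estimate was 0.647, far above the preset 0.01, so the camera p at the preset correlation may be much too small. Markers of pericytes and smooth muscle cells had a median of 0.007 over 15 genes, or -0.016 after quantile normalisation of the deposited values and -0.011 after median centring, and did not pass (adjusted p = 0.81). Of these, ABCC9 was at 2.22 ± 0.37 (adjusted p = 0.145) and RGS5 at -0.99 ± 0.21 (adjusted p = 0.204), or -0.63 with the mean of its 5 probe sets. Adipocyte markers moved the other way, higher in forskolin by a median of 1.51. Between forskolin replicates 1 and 2, contractile genes were lower in replicate 1 for 21 of 21 (median -0.39) and adipocyte markers higher for 22 of 23 (median 1.43), whereas between vehicle replicates 1 and 2 both were higher in replicate 1, for 16 of 21 (median 0.17) and 23 of 23 (median 1.54).

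Adipocyte markers were higher after forskolin, with a median log2 fold change of 1.51 over 23 genes, 21 of them higher, and LEP, the leptin gene, was the clearest exception. By limma 0 of the 23 passed over all genes tested and 7 had an unadjusted p under 0.05, and 1 rose and 1 fell when adjusted over the list alone. ADIPOQ, which encodes adiponectin, was at 12.52 ± 0.99 (SD, n = 2) in vehicle and 14.03 ± 0.61 in forskolin, a difference of 1.51 ± 0.56 (adjusted p = 0.353). LEP was at -2.35 ± 0.29 (adjusted p = 0.0775), 5.09-fold lower. The lipid droplet protein gene PLIN1 was at 1.24 ± 0.69 (adjusted p = 0.499), the hormone-sensitive lipase gene LIPE at 2.16 ± 0.79 (adjusted p = 0.353), the fatty acid carrier gene FABP4 at 0.36 ± 0.17 (adjusted p = 0.438; 0.92 with the mean of its 2 probe sets, adjusted p = 0.403) and the adipogenic receptor gene PPARG at 0.59 ± 0.53 (adjusted p = 0.669). The list passed camera (adjusted p = 5.41e-05) but not without vehicle replicate 2 (median 0.59, adjusted p = 0.0931), its median was 0.97 without forskolin replicate 1, and its adjusted p was 0.879 with an estimated correlation. The markers also differed between replicates, by a median of 1.54 log2 between vehicle replicates 1 and 2 and of 1.43 between forskolin replicates 1 and 2, higher in replicate 1 for 23 and 22 of the 23.

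Thermogenic and beige adipocyte genes did not pass as a list, with a median of 0.40 over 19 genes (adjusted p = 0.0584). It did pass camera with the filter at the 50th percentile (median 0.88, adjusted p = 0.0129) and after median centring (0.39, adjusted p = 0.042). The list did not pass with the mean of all probe sets (0.26, adjusted p = 0.0867), without the filter (0.26, adjusted p = 0.0533) or after quantile normalisation (0.40, adjusted p = 0.0655). With an estimated correlation its adjusted p was 0.879, and its median was 0.38 without vehicle replicate 2. By limma 0 of the 19 passed over all genes tested and 7 had an unadjusted p under 0.05, and 3 rose when adjusted over the list alone. The lipid droplet gene CIDEA was 7.89-fold higher (2.98 ± 0.49, adjusted p = 0.138), the mitochondrial coactivator gene PPARGC1A 5.18-fold higher (2.37 ± 0.49, adjusted p = 0.195) and DIO2, the deiodinase that activates thyroid hormone, 4.59-fold higher (2.20 ± 0.46, adjusted p = 0.196). The 5 DIO2 probe sets ranged from 0.12 to 2.20, with 1.20 for their mean (adjusted p = 0.245). For each of these 3 genes both forskolin values lay above both vehicle values. UCP1, the uncoupling protein of brown and beige fat, was left out of the test by the filter on dim probe sets. Its single probe set read 4.85 and 4.93 on the vehicle arrays, 9.51 on forskolin replicate 1 and 5.04 on forskolin replicate 2. Tested without the filter, it was at 2.38 ± 1.46 (adjusted p = 0.579).

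**Figure D2:**
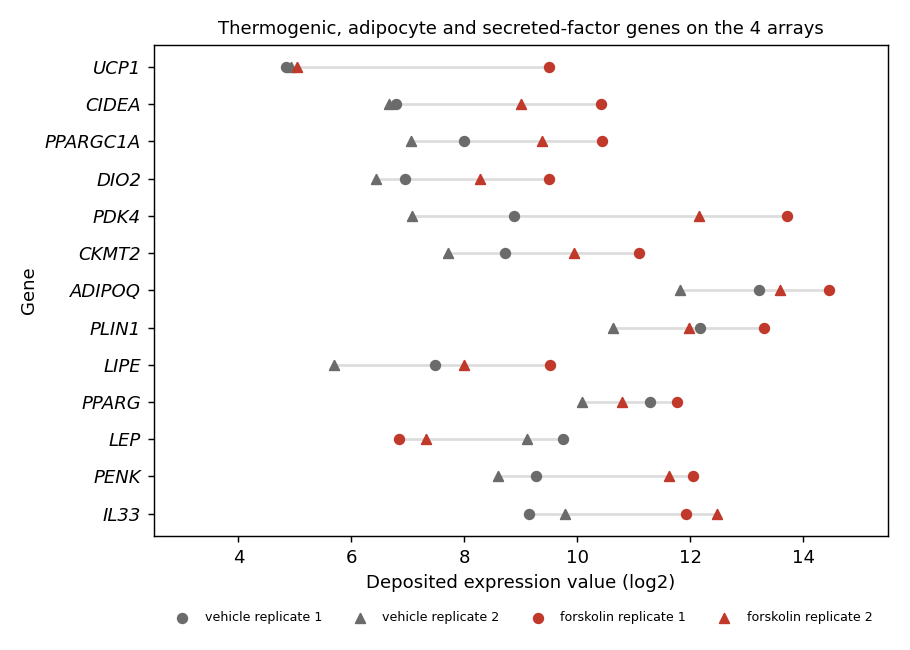
Deposited log2 expression value (x axis) of thermogenic, adipocyte and secreted-factor genes (y axis) on the 4 arrays; each point is 1 array, grey for vehicle and red for forskolin, with circles for replicate 1 and triangles for replicate 2. UCP1 stands at 9.51 on forskolin replicate 1 and between 4.85 and 5.04 on the other 3 arrays, and LEP is lower on both forskolin arrays.

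Genes of mitochondrial respiration and fat metabolism were higher after forskolin as lists, although by limma 0 of their members passed over all genes tested. At an unadjusted p under 0.05 there were 32 genes of respiration, 8 of fatty acid oxidation, 3 of lipolysis and 2 of fat synthesis. All 45 measured respiratory chain genes were higher, with a median of 0.50 log2 or 1.42-fold, and 25 rose when adjusted over the list alone. ATP5F1B, a subunit of ATP synthase, was at 0.84 ± 0.17 (adjusted p = 0.195) and UQCRC1, of complex III, at 1.04 ± 0.22 (adjusted p = 0.198). Of 23 fatty acid oxidation genes 22 were higher, with a median of 0.65 and 0 past when adjusted over the list alone, and PDK4, the kinase that inhibits pyruvate dehydrogenase, was at 4.95 ± 0.81 (adjusted p = 0.136). Lipolysis and lipid droplet genes had a median of 0.57 over 16 genes, 1 of which rose when adjusted over the list alone. Fatty acid and triglyceride synthesis genes had a median of 0.61 over 21 genes, none past when adjusted over the list alone, with DGAT1 at 1.30 ± 0.39 (adjusted p = 0.29). By camera the adjusted p was 8.9e-18 for respiration, 3.23e-07 for oxidation, 0.0126 for lipolysis and 0.0161 for synthesis. With an estimated correlation the adjusted p was 0.924 for synthesis and 0.879 for the other 3 lists. The estimate was 0.918 for respiration, 0.755 for oxidation, 0.519 for lipolysis and 0.977 for synthesis, far above the preset 0.01. The camera p-values at the preset correlation may therefore be much too small for these lists. The synthesis list was at a median of -0.013 without vehicle replicate 2 (adjusted p = 0.601) and 0.065 without forskolin replicate 1 (adjusted p = 0.567), and lipolysis at 0.16 (adjusted p = 0.334) and 0.26 (adjusted p = 0.252). Without vehicle replicate 1 or forskolin replicate 2 the medians were higher, at 1.41 and 1.24 for synthesis and 0.93 and 0.98 for lipolysis. Adipocyte markers moved with these lists (median 1.51), for lipolysis and synthesis in part through shared members. Of the lipolysis genes 8 of 16, and of the synthesis genes 5 of 21, also stand in another list. No oxidation or respiration gene does. The lists also differed between replicates. Between forskolin replicates 1 and 2, synthesis genes were higher in replicate 1 for 21 of 21 (median 1.14), oxidation genes for 22 of 23 (median 0.84), lipolysis genes for 14 of 16 (median 0.93) and respiration genes for 45 of 45 (median 0.38). The oxidation and respiration lists passed without any 1 array, with medians from 0.37 without forskolin replicate 1 to 1.12 without forskolin replicate 2 and from 0.33 to 0.68 for the same arrays.

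**Figure D3:**
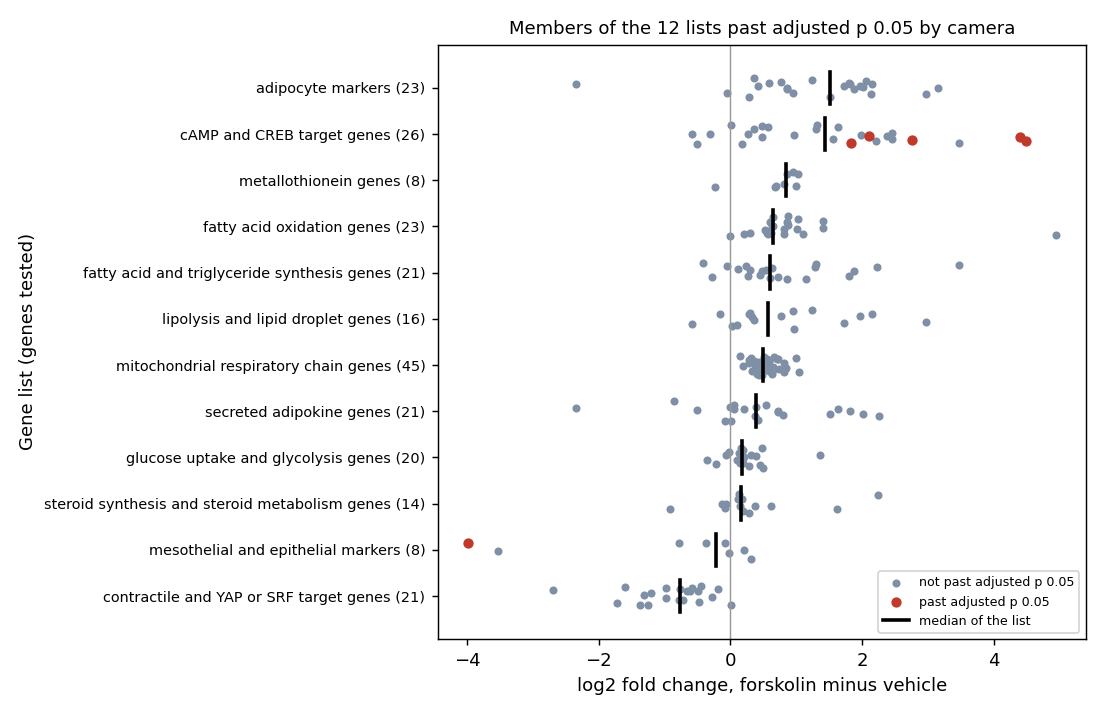
Log2 fold change, forskolin minus vehicle (x axis), of the members of the 12 lists that passed camera at an adjusted p under 0.05 (y axis, with the number of genes tested); each point is 1 gene, red where the gene itself passed over all genes tested, and the black bar is the list's median. The medians run from 1.51 for adipocyte markers to -0.76 for contractile and YAP or SRF target genes, and 5 red points lie among the cyclic AMP targets and 1, KRT19, among the mesothelial and epithelial markers.

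The other lists that passed camera had smaller medians or few members. Metallothionein genes, which encode metal-binding proteins, had a median of 0.84 over 8 genes (adjusted p = 1.84e-05, but adjusted p = 0.879 with an estimated correlation), 5 of which rose when adjusted over the list alone. Over all genes tested limma called 0 members of the metallothionein, adipokine, glycolysis and steroid lists, with 6, 8, 4 and 4 at an unadjusted p under 0.05. MT2A was at 0.95 ± 0.14 (adjusted p = 0.104) and MT1G at 1.00 ± 0.13 (adjusted p = 0.0856), on probe sets that can cross-hybridise between family members. Secreted adipokine genes had a median of 0.40 over 21 genes (adjusted p = 0.0159, but adjusted p = 0.879 with an estimated correlation), with 5 up and 1 down when adjusted over the list alone, and SFRP4, a secreted Wnt modulator, was at 2.27 ± 0.34 (adjusted p = 0.12). Of the 21, 6 also stand in another list, and the adipocyte markers were higher by a median of 1.51. Glucose uptake and glycolysis genes had a median of 0.17 over 20 genes (adjusted p = 0.00819, but adjusted p = 0.879 with an estimated correlation), none past when adjusted over the list alone. Steroid synthesis and metabolism genes had a median of 0.16 over 14 genes (adjusted p = 0.0336, but adjusted p = 0.879 with an estimated correlation), 1 of which rose when adjusted over the list alone, with HSD11B1, which regenerates cortisol, at 2.25 ± 0.25 (adjusted p = 0.0667). Mesothelial and epithelial markers had a median of -0.23 over 8 genes (adjusted p = 0.0336, but adjusted p = 0.879 with an estimated correlation). Of these KRT19 fell over all genes and 2 fell when adjusted over the list alone. The estimated correlation was -0.0141 for adipokine, -0.0292 for steroid and -0.0337 for mesothelial genes, below the preset 0.01. It therefore does not account for the higher adjusted p of those lists. It was 0.785 for metallothionein and 0.269 for glycolysis genes. Without vehicle replicate 2 the adipokine (adjusted p = 0.0931), glycolysis (adjusted p = 0.334) and steroid (adjusted p = 0.207) lists did not pass, nor did steroid genes without forskolin replicate 1 (adjusted p = 0.064) or glycolysis without forskolin replicate 2 (adjusted p = 0.169). The medians ranged from 0.21 without vehicle replicate 2 to 0.63 without forskolin replicate 2 for adipokine genes, and from 0.098 without forskolin replicate 2 to 0.28 without vehicle replicate 1 or forskolin replicate 1 for glycolysis genes. For steroid genes the median was 0.27 without vehicle replicate 1 or forskolin replicate 2. Mesothelial markers did not pass without vehicle replicate 1 (adjusted p = 0.0719), without forskolin replicate 2 (adjusted p = 0.103) or without cross-hybridising probe sets, a setting chosen after the data were seen (median -0.056, adjusted p = 0.394). Their median was -0.50 without vehicle replicate 2, -0.38 without forskolin replicate 1, -0.37 with the filter at the 50th percentile and -0.089 without the filter.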

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

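The test without cross-hybridising probe sets (suffix _x_at) was chosen after the data were seen; the other alternatives were planned. The 71 calls (36 higher, 35 lower) became 83 after quantile normalisation of the deposited values, 82 after median centring and 84 without the filter, which kept 70, 71 and 71 of them. The filter at the 50th percentile gave 45 (21 lower) of 12789 genes tested, the mean of all probe sets 51 (20 lower), every probe set on its own 98 (57 higher, 41 lower), and an adjusted p under 0.1 gave 222 (96 higher, 126 lower). Leaving out 1 array gave 0 to 229 calls, 0 to 88 higher and 0 to 141 lower, with the lone array of a group assumed to vary like the other group. The lowest were without a vehicle array and the highest without forskolin replicate 2; the cause was not tested. At an unadjusted p under 0.05 these fits had 1168 to 3086 genes. With the replicate block 1333 genes passed, 711 higher and 622 lower, all 71 among them, and 14 lists, with thermogenic genes (adjusted p = 0.00359) and cholesterol synthesis genes (adjusted p = 0.0035) added, and 18 adipocyte markers passed higher and 1 lower (list adjusted p = 1.33e-15). The samples share only a number: over genes, the difference of vehicle replicates 1 and 2 correlated with that of forskolin replicates 1 and 2 at 0.598. Of the 12 lists past camera, 0 passed with an estimated correlation and 1 with fry. The 12 became 8 to 14 when 1 array was left out. Without the filter steroid genes did not pass (adjusted p = 0.115).

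No named gene past the threshold changed direction under an alternative run for single genes, which left out CREM. Every probe set on its own was run for counts only; among the named genes past the threshold, RORA had a probe set of opposite sign (-0.28). PPARG, which did not pass, ranged from -0.01 to 1.20 when 1 array was left out. Of the 12 lists past camera, fatty acid and triglyceride synthesis changed sign, from 0.61 to -0.013 without vehicle replicate 2 (1.41 without vehicle replicate 1). Synthesis genes were higher in vehicle replicate 1 than in vehicle replicate 2 for 21 of 21 (median 1.73), so this median depended on which vehicle array was kept. The other lists whose medians changed sign had not passed, and the cause of their changes was not tested. Endothelial markers went to -0.002 and pericyte and smooth muscle markers to -0.016 after quantile normalisation, and the latter to -0.011 after median centring, -0.041 with the mean of all probe sets and -0.065 without cross-hybridising probe sets. Without the filter circadian genes went to -0.031, and with the filter at the 50th percentile to -0.031, with cyclic AMP components at -0.017 and TGF-beta and BMP genes at 0.049. Skeletal muscle markers were at -0.002 with the mean of all probe sets, and glucocorticoid targets at -0.088 without cross-hybridising probe sets. When 1 array was left out, medians ranged from -0.027 to 0.099 for cyclic AMP components, -0.18 to 0.078 for extracellular matrix, -0.26 to 0.17 for TGF-beta and BMP, -0.35 to 0.023 for interferon response, -0.089 to 0.15 for glucocorticoid targets, -0.094 to 0.14 for circadian genes, -0.044 to 0.16 for cell cycle, -0.020 to 0.17 for ER stress and -0.079 to 0.20 for hypoxia. For cell types they ranged from -0.20 to 0.39 for progenitors and fibroblasts, -0.051 to 0.14 for endothelial, -0.071 to 0.048 for pericyte and smooth muscle, -0.16 to 0.22 for skeletal muscle and -0.30 to 0.13 for osteoblast and chondrocyte markers. Genes near the background, such as UCP1 on 3 arrays, have fold changes that may be understated, which was not tested.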

Other observations

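Interferon response genes had a median of -0.11 over 20 genes and did not pass camera (adjusted p = 0.0559), with 1 higher and 6 lower when adjusted over the list alone. IFIT3 was at -1.38 ± 0.13 (adjusted p = 0.0539) and IFIT1 at -1.73 ± 0.18 (adjusted p = 0.0631), both interferon-induced antiviral genes. Without vehicle replicate 2 the list passed at a median of -0.35 (adjusted p = 0.00328), and without vehicle replicate 1 the median was 0.023. It also passed without the filter (-0.13, adjusted p = 0.0296), with the filter at the 50th percentile (-0.21, adjusted p = 0.0165), with the mean of all probe sets (-0.18, adjusted p = 0.0233) and without cross-hybridising probe sets (-0.19, adjusted p = 0.0446), a setting chosen after the data were seen. It did not pass after quantile normalisation (adjusted p = 0.0655), after median centring (adjusted p = 0.072) or with an estimated correlation (adjusted p = 0.879). The clock gene RORA rose by 1.75 ± 0.15 log2 (adjusted p = 0.0469), although 1 of its 6 probe sets had the opposite sign and the mean of all of them gave 1.25 (adjusted p = 0.104). The 15 clock genes had a median of 0.037 and a mean of -0.016 (adjusted p = 0.906). ADM, the adrenomedullin gene, was at -1.37 ± 0.13 (adjusted p = 0.0511). The remaining function lists did not pass in the comparison as reported. Their medians were 0.39 for cholesterol synthesis (adjusted p = 0.205), 0.086 for creatine and calcium cycling (adjusted p = 0.575), -0.032 for extracellular matrix (adjusted p = 0.91), 0.034 for glucocorticoid targets (adjusted p = 0.794) and 0.060 for cell cycle genes (adjusted p = 0.36). ER stress genes were at 0.077 (adjusted p = 0.585) and ribosomal protein genes at -0.076 (adjusted p = 0.0559). Hypoxia genes had a median of 0.075 and a mean of -0.048 (adjusted p = 0.881), and complement genes a median of -0.058 and a mean of 0.036 (adjusted p = 0.575). Some of these lists passed under single alternatives. Ribosomal protein genes did after median centring (adjusted p = 0.0295), without the filter (adjusted p = 0.046) and without forskolin replicate 2 (adjusted p = 0.009). Cholesterol synthesis genes did without vehicle replicate 1 (adjusted p = 0.00423) and without forskolin replicate 2 (adjusted p = 0.00613). Extracellular matrix genes did without forskolin replicate 2 (adjusted p = 0.0267), ER stress genes without forskolin replicate 1 (adjusted p = 0.0353) and cell cycle genes without vehicle replicate 2 (adjusted p = 0.033).

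The mesothelial and epithelial markers passed as a list, and, besides the pericyte and smooth muscle markers, those of 5 other cell types did not with all 4 arrays. Progenitor and fibroblast markers had a median of 0.034 over 19 genes (adjusted p = 0.585), endothelial markers 0.019 over 12 (adjusted p = 0.647), or -0.002 after quantile normalisation of the deposited values, and leukocyte markers -0.11 over 13 (adjusted p = 0.314). Progenitor markers passed without forskolin replicate 1 (0.39, adjusted p = 0.0257) and leukocyte markers without vehicle replicate 1 (-0.20, adjusted p = 0.0321). Skeletal muscle markers had a median of 0.026 and a mean of -0.003 over 6 genes (adjusted p = 0.975), and osteoblast and chondrocyte markers a median of -0.074 and a mean of 0.11 over 9 (adjusted p = 0.838), with SOX9 at 1.26 ± 0.14 (adjusted p = 0.0664). The keratin gene KRT18, the partner of KRT8 in simple epithelia, was at -3.53 ± 0.50 (adjusted p = 0.102) beside the fall of KRT19. The 2 arrays of a group also differed in whole gene groups. Fatty acid and triglyceride synthesis genes were higher in replicate 1 for 21 of 21 genes in both groups, by a median of 1.73 log2 in vehicle and 1.14 in forskolin. Respiratory chain genes were higher in replicate 1 for 41 of 45 genes in vehicle (median 0.086) and 45 of 45 in forskolin (median 0.38), and contractile genes lower in forskolin replicate 1 than in replicate 2 for 21 of 21 (median -0.39). The tests of explanations in the paragraphs below were chosen after the results were seen, except the count of extreme probe sets per array.

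UCP1 stood 4.47 log2 units, or 22.2-fold, higher on forskolin replicate 1 than on forskolin replicate 2, which read 5.04 against 4.85 and 4.93 in vehicle. The value on forskolin replicate 2 lies below the filter floor, so the difference may be understated. An array-wide fault of the forskolin replicate 1 array would put many scattered probe sets far above the other arrays, but 3 of 54614 stood at least 3 log2 units above the other 3 arrays. The UCP1 difference was larger than that of any of the 23 adipocyte markers, of which the largest was 1.96, for SLC7A10. That size does not decide whether the forskolin replicate 1 culture held a larger share of differentiated adipocytes. PCK1, a fat synthesis gene outside the markers, read 11.98 and 8.10 on forskolin replicates 1 and 2. On vehicle replicates 1 and 2 it read 8.91 and 4.22, a gap of similar size without forskolin. A fault at this single probe set stays open, because no second UCP1 probe set was measured. A difference between the cultures in their thermogenic response, for example between individuals, may also account for it and was not tested.

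The adipocyte markers were higher after forskolin by a median of 1.51 log2 while LEP was lower. A larger share of adipocytes in the forskolin cultures would by itself raise LEP with the rest. The upper 95% limit of the log2 fold change of LEP was -1.57, so a larger share alone does not account for LEP. LEP does not decide whether the share was larger, because a separate fall of LEP could hide it. For the other markers, the progenitor and fibroblast markers had a median of 0.03 with limits of -0.10 to 0.28 from resampling genes. Between replicates 1 and 2 those markers were lower in replicate 1, with medians of -0.45 in vehicle and -0.78 in forskolin. Adipocyte markers were higher there, by 1.54 and 1.43. The progenitor markers did not fall in this way after forskolin. That does not tell a larger share apart from a response within adipocytes. Whether forskolin itself moves progenitor markers was not tested, and their median ranged from -0.20 to 0.39 when 1 array was left out. Of the adipocyte markers, 9 of 23 had both forskolin values above both vehicle values, where chance gives 16.7% for a single gene. This count ignores the replicate number, and the markers were higher in replicate 1 for 23 of 23 in vehicle and 22 of 23 in forskolin. With the replicate number as a block, limma called 18 markers higher and 1 lower. A chance spread of differentiation between cultures stays open, because these markers vary together and there are 2 cultures per group. The labels also do not say that a replicate number stands for an individual. Of the 23 markers, 15 also stand in another list.

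Contractile and YAP or SRF target genes were lower after forskolin, with a median of -0.76 log2. Fewer pericytes or smooth muscle cells in the forskolin cultures would lower the markers of those cells as far, but the 13 such markers outside the contractile list had a median of 0.09 and quartiles of -0.20 and 0.76, and 12 of the 13 lay above the contractile median. The lists differed by a two-sided permutation test over genes (p = 1e-05, the smallest that 100000 resamples can give), which treats genes as independent. A larger share of adipocytes in the forskolin cultures, whose markers were higher by a median of 1.51, was not tested for this list and stays open, as does a response within the cells. Differences between replicates 1 and 2 do not decide it. In vehicle, contractile genes and adipocyte markers were both higher in replicate 1 (medians 0.17 and 1.54). In forskolin, contractile genes were lower and adipocyte markers higher in replicate 1 (medians -0.39 and 1.43).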
